A study of Mus musculus with 483 samples.

How the data were processed

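The series holds 483 mouse cells, 239 labelled Ctrl and 244 labelled aDll4-treated. Each cell carried CD31 and Kit, lacked CD45 by flow cytometric sorting, and came from the aorta with the surrounding gonads and mesonephros. The labels do not explain aDll4. Per the labels' protocols, cells were sorted into lysis buffer, cDNA was made and amplified by the Smart-seq2 method, Nextera XT libraries were built from it, and pools were sequenced on an Illumina HiSeq instrument. Smart-seq2 reads cover whole transcripts, carry no molecular identifiers and do not mark the strand.

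The deposited table holds whole-number counts of reads per gene and cell, not normalised. Per the submitters' processing notes, the build was mm10 and the tools were GSNAP, a read aligner, and HTSeq 0.6.0, which counts reads per gene. The annotation release, the counting settings and any filter on cells are not given in the sources used here. The table has 46078 genes, and columns of no sample numbered 0. No pair of columns was identical. Gene symbols and positions were taken from GENCODE M21 on the same build by Ensembl identifier. A symbol was found for 45143 identifiers. Another 935 had none and were known by identifier only, as were 112 identifiers whose symbol was shared.

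Gene-assigned reads per cell ranged from 136928 to 2870618 in Ctrl (median 900286) and from 123097 to 2451790 in treated cells (median 869802). Every cell of the table was used, no cell filter was added, and doublets were not called. A sorting well that received more than 1 cell would therefore remain.

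The labels name no embryo, animal or culture. Cells are not replicates, so each treatment counted as 1 sample, no test between treatments was run, and no p-value is given. Reads of Xist and Y-linked genes show cells of more than 1 embryo but not how many, and groups drawn from them were not used as replicates. Levels are counts summed over the cells of a treatment, scaled to the summed gene-assigned total (CPM), with exact Poisson 95% intervals. Shares of cells with 1 read or more have exact Clopper-Pearson 95% intervals. Differences between shares have Newcombe 95% intervals. All of these cover counting error only, and amplified reads are not independent molecules. They do not cover the spread between embryos. The size of a difference is the log2 ratio of treated over Ctrl CPM with 1 CPM added to both, which understates differences of low genes. The mean over cells of log2(CPM + 1) is given with its SD over cells. Where a share is 0, the limit given is that of 3 counts.

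A gene was measured if at least 5% of all cells had a read of it, which held for 15204 genes. The 28 gene lists and the naming rule were fixed before the data were examined. For a list, the median log2 ratio of its measured members was set among the medians of 10000 random lists of the same size, drawn from the same 20 bins of expression level. Its percentile describes these libraries and is no test. A median is called outside the matched lists when it lay beyond their central 95%.

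The lists were Notch target genes, Notch receptors with ligands and modifiers, arterial endothelium, venous endothelium, pan-endothelial genes, endothelial tip cells, endothelial-to-hematopoietic transition factors, hematopoietic stem cells, pan-hematopoietic genes, S phase, G2 and M phase, cell cycle inhibitors, p53 targets, immediate early and heat shock genes, glycolysis and hypoxia, interferon response, BMP and TGF-beta targets, mesenchymal transition and adhesion, erythroid, myeloid, megakaryocyte and lymphoid cells, mesenchyme and smooth muscle, mesonephric and gonadal epithelium, primordial germ cells, neural crest and neurons, sex-linked genes, and the genes of the sorting gate. The Notch target and arterial lists share 4 genes (Efnb2, Gja5, Hey1 and Hey2). Another 2 lists, MYC targets of ribosome biogenesis and NF-kappaB targets without Birc3 and Nfkbia, were added after the data were seen.

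Named genes had a symbol that was not a predicted name, were not sex-linked, and had a read in at least 10% of the cells of a treatment. Their difference had to point the same way in summed CPM, in mean log2(CPM + 1) and in the share of cells. It also had to do so in both blocks of library numbers and in at least 5 of the 6 runs of numbers, as judged by mean log2(CPM + 1), so that the ratio of summed CPM of a named gene can differ in sign in a block or run. Of 2156 genes that met this, the 12 highest and 12 lowest by difference in mean log2(CPM + 1) are named. Within clusters the condition on runs was dropped and 4 were named each way. From each list, members with the largest difference in mean log2(CPM + 1) are named, and Dll4, Notch1, Hes1, Hey1, Hey2, Runx1, Gfi1, Kit, Pecam1 and Ptprc always.

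Library numbers in the labels fall into 2 blocks, below 20000 (block 1: 176 Ctrl and 178 treated cells) and above 22000 (block 2: 63 and 66 cells). They were cut into 6 runs of 96 consecutive numbers, each with cells of both treatments. The labels do not say that runs were plates. Comparisons were repeated within blocks and runs.

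The submitters' labels place each cell in 1 of 7 clusters. For shares, cells were also reassigned to the cluster centroid of Ctrl cells with which they correlated best, over the 50 leading genes of each cluster. The Notch lists and the named genes were left out there, and each Ctrl cell was left out of its own centroid. Comparisons within clusters were made for the 3 clusters with at least 30 cells in each treatment.

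Alternatives were equal weight per cell, the mean of log2(CPM + 1), pseudocounts of 0.1 and 10 CPM, cells thinned to 200000 reads, scran size factors, totals without mitochondrial genes and the 50 most abundant genes, each block alone, each run left out, the highest cell of each gene left out, equal cluster shares, other detection limits, and the reassigned clusters. Thinning left out 8 Ctrl and 3 treated cells. Added after the data were seen were splits by sex, taken from 10 or more reads of Xist or of 4 Y-linked genes in sum, and comparisons without clusters 4 and 5 or 6 and 7. The median log2 ratio of all measured genes was 0.012, and the farthest from 0 in any setting was 0.055.

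The functions were tested on simulated counts with the real gene levels and library sizes for aDll4-treated against Ctrl. Of 15204 simulated genes, 200 were changed. For changes of 1 and -1 in log2, medians of 0.95 and -0.99 were recovered, and for 2 and -2, medians of 1.93 and -1.87. All 24 genes named by the rule were truly changed ones. Every simulated change was at least 1 in size, larger than the ratios of several real named genes, such as Trmt6 (0.42) and Sparcl1 (-0.48). Naming at such smaller changes was therefore not tested. Of 200 lists of unchanged genes, 4.0% lay outside the central 95%. The simulation had no differences between embryos, and its genes varied independently, so the 4.0% does not hold for genes that vary together. Without treatment, Xist-positive over Y-positive Ctrl cells of block 1 gave pan-hematopoietic genes a median of 0.86, outside their matched lists (-0.21 to 0.24). Transition factors (0.68), S phase genes (0.18) and p53 targets (-0.32) were among the other lists outside theirs there. Further lists, such as the arterial (-0.015), lay within theirs in block 1. In block 2 the arterial median of this contrast was 0.30, outside its matched lists (-0.28 to 0.28). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, and R 4.3.3 with scran 1.30.0 for the size factors.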

Results

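Single-cell transcriptomes were measured in mouse cells that carried the endothelial marker CD31 and the stem cell factor receptor Kit and lacked the blood marker CD45. They came from the aorta-gonad-mesonephros region, where hematopoietic stem cells emerge from hemogenic endothelium. The series title concerns the Notch ligand Dll4, the entry of hemogenic cells into clusters within the aorta, and stem cell output. The data compare Ctrl cells with aDll4-treated cells, and the labels do not explain aDll4. The 6 runs of library numbers held 46, 46, 44, 40, 37 and 26 Ctrl cells and 46, 46, 39, 47, 30 and 36 treated cells. Each treatment is 1 sample for lack of any label of embryo or culture, so no difference below was tested against the spread between embryos. Total gene-assigned reads were 223958669 in Ctrl and 218588875 in treated cells. Median genes with a read per cell were 7459 and 7623.5, or 6407 and 6559 after thinning to equal depth. The median mitochondrial share of reads was 8.25% in Ctrl and 7.93% in treated cells.

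Most cells were endothelial. The genes below identify the submitters' 7 clusters, which were built on these same cells, and are no findings. Clusters 1, 2 and 3 held most cells of both treatments and abundant endothelial transcripts. Cdh5, the endothelial cadherin, reached 385, 338 and 275 CPM there, against at most 8.83 CPM in clusters 4 to 7. Cluster 1 carried the most Dll4 (475 CPM) and Igfbp3 (1725 CPM). Cluster 2 had more of the apelin receptor Aplnr (990 CPM) and of Sox17 (355 CPM). Cluster 3 had the fewest genes per cell. The hematopoietic repressor Gfi1 was highest there (21.1 CPM), but only 9.68% of its Ctrl and 8.33% of its treated cells had a read of it. The mean log2(CPM + 1) of the transition factor list was 1.94 in cluster 3, no higher than in clusters 1 and 2 (2.04 and 2.00). Clusters 4 and 5, with 22 and 13 cells, carried mesenchymal transcripts. Pdgfra stood at 197.4 CPM in cluster 4, and Acta2, smooth muscle actin, at 4639 CPM in cluster 5. Clusters 6 and 7, with 33 and 20 cells, were hematopoietic. Rac2, a GTPase of blood cells, reached 475 and 278 CPM, and Pf4, a platelet protein, reached 6875 CPM in cluster 7. Ptprc, which encodes CD45, was at most 0.89 CPM in any cluster.

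The first comparison asked which genes differed between treated and Ctrl cells. Dll4 itself (ENSMUSG00000027314, mm10 chromosome 2, 119325784 to 119335962, plus strand) was lower in treated cells. It stood at 356 CPM in Ctrl (95% interval 353 to 358) and 177.2 CPM in treated cells (175.4 to 178.9). The log2 ratio was -1.15 in block 1 and -0.46 in block 2, and it was below 0 in 6 of 6 runs. Its receptor Notch1 had a log2 ratio of -0.64, with -0.82 in block 1 and 0.10 in block 2. The Notch-responsive repressors Hes1 and Hey1 had log2 ratios of -0.76 and -1.11. Hes1 was lower in 6 of 6 runs. Hey1 was lower in block 1 (-2.03) and higher in block 2 (0.86). Hey2, with a read in 8.79% of Ctrl and 6.97% of treated cells, had a log2 ratio of -0.063.

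Across the Notch target list, 6 of the 9 measured genes were lower and 3 were higher in treated cells. The median log2 ratio was -0.65. Of 10000 matched random lists, 0 had a median this low, and the median was below 0 in 6 of 6 runs. By mean log2(CPM + 1), the largest differences were in Hey1, Nrarp, Efnb2 and Hes1. Nrarp, a feedback regulator of Notch signalling, had a read in 52.7% of Ctrl cells (46.2 to 59.2%) and 34.4% of treated cells (28.5 to 40.8%). Its log2 ratio was -0.90. Efnb2, the arterial ligand ephrin B2, was at 60.8 CPM in Ctrl and 38.4 CPM in treated cells. The list of Notch receptors, ligands and modifiers showed no such shift as a set, with 8 genes higher, 8 lower and a median of -0.013.

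Most arterial genes were lower. Of the 17 measured genes of the arterial list, 15 were lower in treated cells, the median log2 ratio was -0.65, and 0 of 10000 matched lists reached it. This equals the Notch target median because Efnb2, 1 of 4 genes on both lists, is the middle gene of each. The arterial median was below 0 in both blocks (-0.59 and -0.39) and in 5 of 6 runs. By mean log2(CPM + 1), Dll4, Hey1, Mecom and the VEGF co-receptor Nrp1 led this list. The log2 ratio of Nrp1 was -0.37, nearer 0 than the median. Not every member was steady. Over 23 settings, Sox17 was above 0 in 16, Cxcl12 in 14, Jag2 and Sox7 in 11 each, Sox18 in 10 and Hey2 in 9. Gja4, Gja5, Efnb2, Dll4, Mecom, Nrp1, Acvrl1 and Unc5b were below 0 in all of them. Mecom (Evi1), a transcription factor of stem cells and arterial endothelium, was at 60.01 CPM in Ctrl and 35.4 CPM in treated cells. The gap junction gene Gja4, chosen after its value was seen, had a log2 ratio of -1.10 and was lower in 5 of 6 runs. Pan-endothelial genes were lower by less. Of 16 genes, 14 were lower, with a median of -0.20 that 0 of 10000 matched lists reached. They include Robo4 (-0.44), Pecam1 (-0.26), Cdh5 (-0.19) and Flt1 (-0.27, but 0.20 in block 2). Pecam1 encodes CD31 and was used in the sort, as was Kit (-0.21), so the gate bears on both. When both treatments were weighted to the same cluster shares, the pan-endothelial median was -0.071 and the arterial median -0.50. Without treatment, Xist-positive over Y-positive Ctrl cells gave pan-endothelial medians of -0.14 in block 1, just outside its matched lists, and 0.17 in block 2. Of 8 venous genes, 7 were lower, with a median of -0.20.

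The 24 genes named by the fixed rule are plotted with their values per run. Among those lower in treated cells besides Dll4 and Mecom were the lymphangiogenic growth factor Vegfc (log2 ratio -1.25), the natriuretic peptide clearance receptor Npr3 (-1.23), and the endothelial phosphatase Ptprb (-0.63). Vegfc had a log2 ratio of -1.88 in block 1 and -0.44 in block 2, and Npr3 -1.55 and -0.61. Vegfc had a read in 41.4% of Ctrl cells (35.1 to 47.95%) and 23.4% of treated cells (18.2 to 29.2%). The potassium channel subunit gene Abcc9 (-1.02), the cholesterol exporter Abca1 (-0.83), BC005561 (-0.53), the ceramidase Acer2 (-0.79), Ptprb and Dll4 were each lower in 6 of 6 runs. The others were Sparcl1 (-0.48), the lysosomal lipase Lipa (-0.84) and Rgs3 (-0.82).

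**Figure D1:**
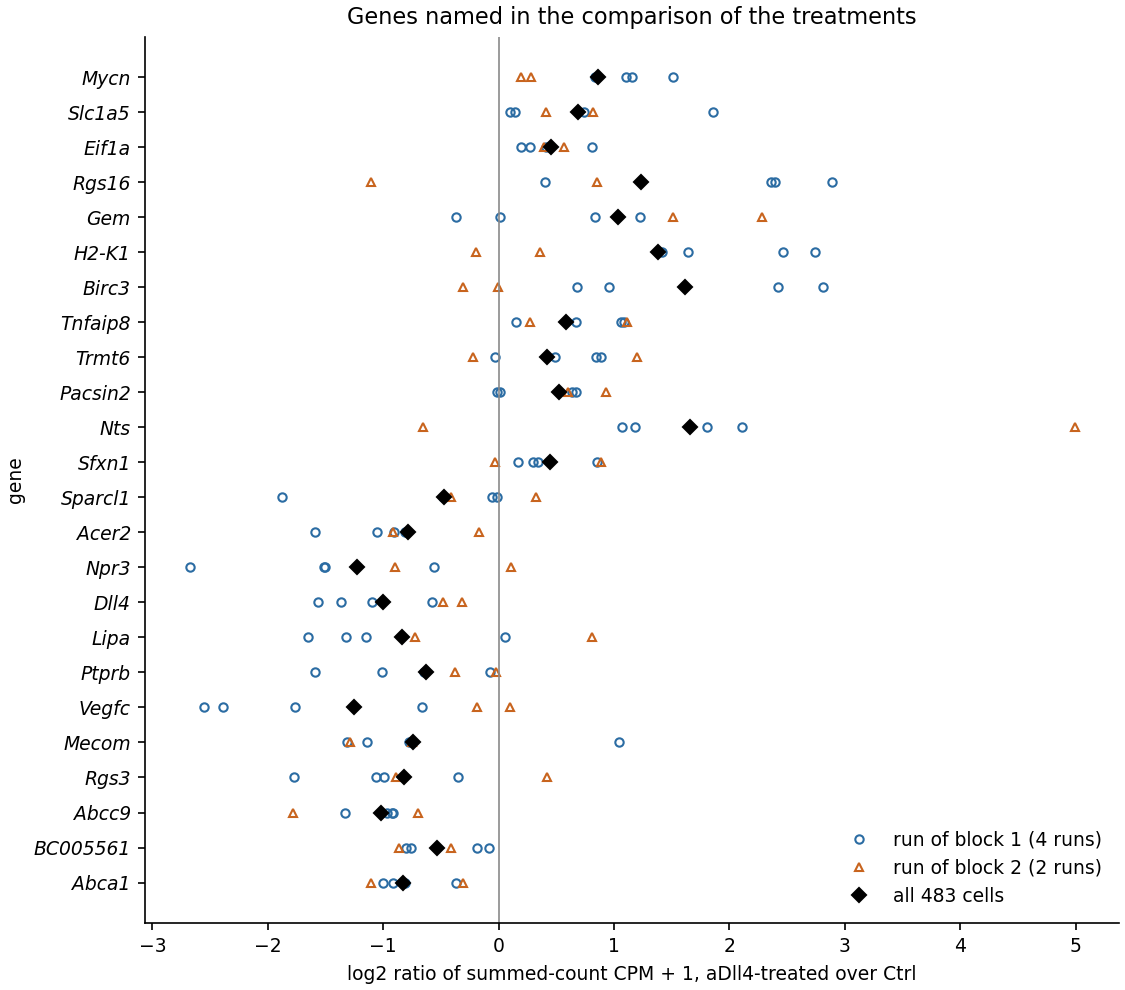
Log2 ratio of summed-count CPM + 1, aDll4-treated over Ctrl (x axis), for the 24 named genes (y axis). Black diamonds are all cells, and open symbols are the 6 runs of library numbers. Mycn, Slc1a5, Eif1a and Tnfaip8 lie above 0 in every run, and Dll4, Acer2, Ptprb, Abcc9, BC005561 and Abca1 below 0 in every run, while Birc3 lies above 0 in 4 runs and Nts spans -0.66 to 4.99.

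Among the genes higher in treated cells, Mycn had the largest difference in mean log2(CPM + 1). This MYC family transcription factor gene (chromosome 12, 12936093 to 12941914, minus strand) was at 77.8 CPM in Ctrl and 142.4 CPM in treated cells, a log2 ratio of 0.86. The ratio was 1.16 in block 1 and 0.072 in block 2. Its mean log2(CPM + 1) was 3.53 ± 3.25 (SD over cells) in Ctrl and 4.94 ± 3.31 (SD over cells) in treated cells. Cells with a read made up 64.02% of Ctrl (57.6 to 70.1%) and 79.9% of treated cells (74.3 to 84.8%). Slc1a5, a glutamine transporter, had a log2 ratio of 0.68, and the translation initiation factor Eif1a 0.46. Tnfaip8 (0.58) was also higher in 6 of 6 runs. Birc3, an inhibitor of apoptosis (1.61), the class I histocompatibility gene H2-K1 (1.38), and Rgs16, which dampens G protein signalling (1.23), were higher in block 1 (2.01, 1.98 and 1.72). In block 2 their ratios were -0.082, 0.22 and -0.15. The small GTPase gene Gem (1.04), the neurotensin gene Nts (1.66), Pacsin2 (0.52), the tRNA methyltransferase subunit Trmt6 (0.42) and the mitochondrial serine transporter Sfxn1 (0.44) complete the set. Eif1a, H2-K1 and the globin genes have close copies in the genome, and read sharing among them leaves their levels uncertain.

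Of 18 S phase genes, 16 were higher in treated cells, with a median of 0.17, and 3 of 10000 matched lists lay as high. The median was -0.29 in run 3, and 0.052 among Xist-positive cells of block 2, within its matched lists. Uhrf1 (0.14), Ccne2 (0.36), Cdc6 (0.42) and Hells (0.34) differed most in mean log2(CPM + 1). Without treatment, Xist-positive over Y-positive Ctrl cells gave S phase medians of 0.18 in block 1 and -0.054 in block 2. The value of block 1 lay outside its matched lists (-0.15 to 0.11). G2 and M phase genes had a median of -0.0066. Of 10 p53 targets, 9 were higher, with a median of 0.27, but the median was -0.014 in block 2. Xist-positive over Y-positive Ctrl cells gave p53 target medians of -0.32 in block 1 and -0.30 in block 2. Cdkn1a, the p21 cell cycle inhibitor, was at 88.05 CPM in Ctrl and 161.9 CPM in treated cells and higher in 6 of 6 runs. Of 12 genes of glycolysis and hypoxia, 10 were higher (median 0.15), among them Hk2 (0.84), while the glucose transporter Slc2a1 was lower (-0.22). This median was below 0 in 2 of 6 runs and -0.013 among Y-positive cells. All 6 interferon response genes were higher (median 0.31), with medians of 0.57 in block 1 and -0.049 in block 2.

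Blood cell genes were higher in treated cells when all cells were pooled. Of 12 pan-hematopoietic genes, 10 were higher (median 0.31), among them Vav1 (0.34), Was (0.77) and Coro1a (0.30). The median was 0.52 in block 1 and near 0 in block 2. The factors of the endothelial-to-hematopoietic transition had a median of 0.16, with 9 of 14 higher, but 0.85 in block 1 and -0.43 in block 2. Runx1, the transcription factor required for this transition, had a read in 24.3% of Ctrl (18.97 to 30.2%) and 28.3% of treated cells (22.7 to 34.4%). Its log2 ratio was 0.31, with 1.15 in block 1 and -0.56 in block 2. Gfi1 was seen in 2.51% of Ctrl and 2.05% of treated cells, too few to compare. Without clusters 6 and 7, the transition factors had a median of -0.21 and the pan-hematopoietic genes -0.12. The hematopoietic stem cell list had a median of -0.18, but 0.033 in block 1 and -0.29 in block 2, and it was above 0 in 3 of 6 runs. Its members went both ways, with Mycn higher and Mecom and Fgd5 (-0.21) lower. Erythroid (0.87), myeloid (0.68) and megakaryocyte (1.12) medians were all above their matched lists. The megakaryocyte median ran from -1.53 to 5.83 over the runs and the myeloid from -0.21 to 2.45, each below 0 in 2 of 6, and the myeloid median was 0.24 in block 1 and 1.22 in block 2. With cells thinned to equal depth the erythroid median was 0.55, and without clusters 6 and 7 the myeloid and megakaryocyte medians were -0.035 and -0.22. Itga2b, a megakaryocyte and early blood integrin, had a log2 ratio of 1.12.

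**Figure D2:**
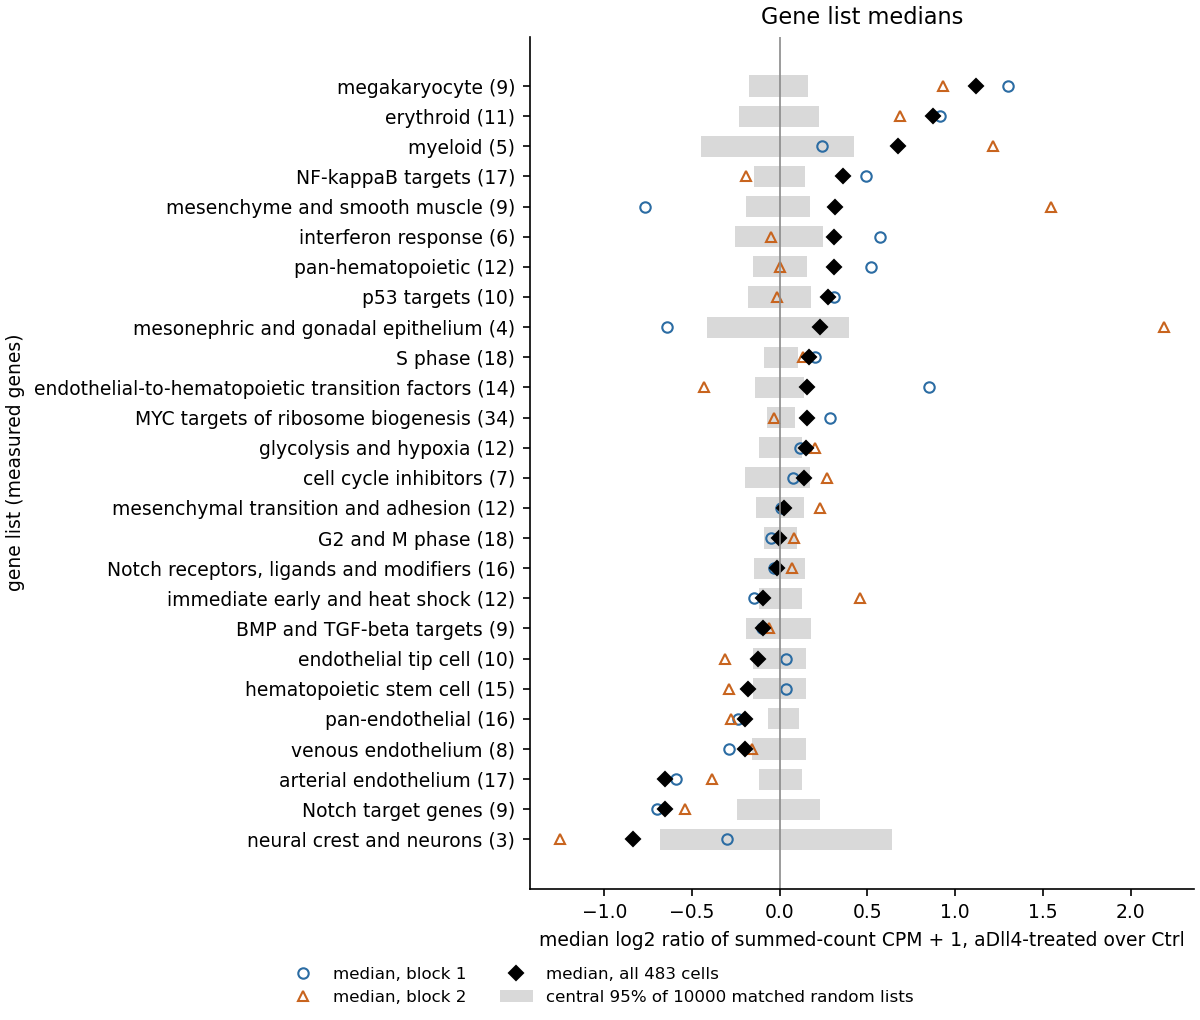
Median log2 ratio of summed-count CPM + 1, aDll4-treated over Ctrl (x axis), of each gene list (y axis, measured genes in parentheses). Diamonds are all cells, circles block 1, triangles block 2, and grey bars the central 95% of 10000 matched random lists over all cells. The Notch target and arterial medians over all cells, both set by the shared gene Efnb2 at -0.65, lie left of their grey bars. Their block medians lie left too, but the bars are not ranges for a block. The transition factors stand at 0.85 in block 1 and -0.43 in block 2.

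Other lists gave smaller or less steady differences. Medians within their matched lists were those of endothelial tip cells (-0.12, with 0.038 in block 1 and -0.31 in block 2), cell cycle inhibitors (0.14), immediate early and heat shock genes (-0.093, with -0.15 and 0.46), BMP and TGF-beta targets (-0.095), and mesenchymal transition and adhesion (0.024). Among tip cell genes, Vegfc, Esm1 (-1.19) and Cxcr4 (-1.78) were lower and Apln (0.78) was higher, but in block 2 Esm1 had 0.12 and Cxcr4 0.72. Of the cell types that the sort could carry along, mesenchyme and smooth muscle had a median of 0.32, with -0.77 in block 1 and 1.55 in block 2. Mesonephric and gonadal epithelium had 4 measured genes and a median of 0.23, with -0.64 in block 1 and 2.19 in block 2. Neural crest and neurons had 3, with a median of -0.83 (0.12 without the highest cell of each gene), lymphoid cells 2, with 0.12 (0.46 in block 1 and -0.29 in block 2), and primordial germ cells 1, at 0.56. The 2 measured genes of the sorting gate, Pecam1 and Kit, had a median of -0.24.

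The treatments also differed in the sex of the cells. By reads of Xist, which female cells express from their inactive X chromosome, and of Y-linked genes, 89.3% of the treated cells of block 1 (83.8 to 93.5%) were Y-positive. These splits were chosen after the data were seen. Xist-positive cells numbered 0 there, which allows a share of up to 1.69%. In block 2, 61 of the 66 treated cells were Xist-positive and 0 were Y-positive, which allows up to 4.55%. Ctrl cells held both kinds, 85 Xist-positive and 77 Y-positive in block 1 and 25 and 29 in block 2. No cell had 10 reads of both. Among Y-positive cells of block 1, the arterial median was -0.48 and the Notch target median -0.91. Among Xist-positive cells of block 2 (25 and 61), they were -0.43 and -0.63. Over the Xist-positive cells of both blocks, where all treated cells were of block 2, the Notch target median was -0.28, within its matched lists, and over all Y-positive cells it was -0.58. Without treatment, Xist-positive over Y-positive Ctrl cells gave Notch target medians of -0.12 in block 1 and 0.60 in block 2. The arterial medians were -0.015 and 0.30, of which the latter lay outside its matched lists (-0.28 to 0.28). Dll4 had log2 ratios of -1.35 and -0.79 in these same-sex comparisons, Mycn 1.26 and 0.33, and Mecom -0.98 and -1.001. Slc1a5 had 1.23 and 0.61, but -0.079 over the Xist-positive cells of both blocks, where all treated cells were of block 2. Without treatment, Xist-positive over Y-positive Ctrl cells gave Dll4 -0.36 in block 1 and 0.50 in block 2, and Mycn 0.18 and -0.48. The same contrast gave Mecom -0.91 and -0.21, Slc1a5 0.83 and -0.40, and Runx1 1.62 and -0.44. Some of these were as large as the ratios for the treatment. Vegfc had -2.21 and -0.092 in the same-sex comparisons, and Trmt6 0.43 and -0.54. Others had opposite signs in block 1 and block 2, with 2.51 and -0.26 for Runx1, 2.30 and -0.92 for Birc3, and 2.001 and -0.54 for H2-K1. The sex-linked list had a median of -0.030, with 0.89 in block 1 and -4.67 in block 2.

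**Figure D3:**
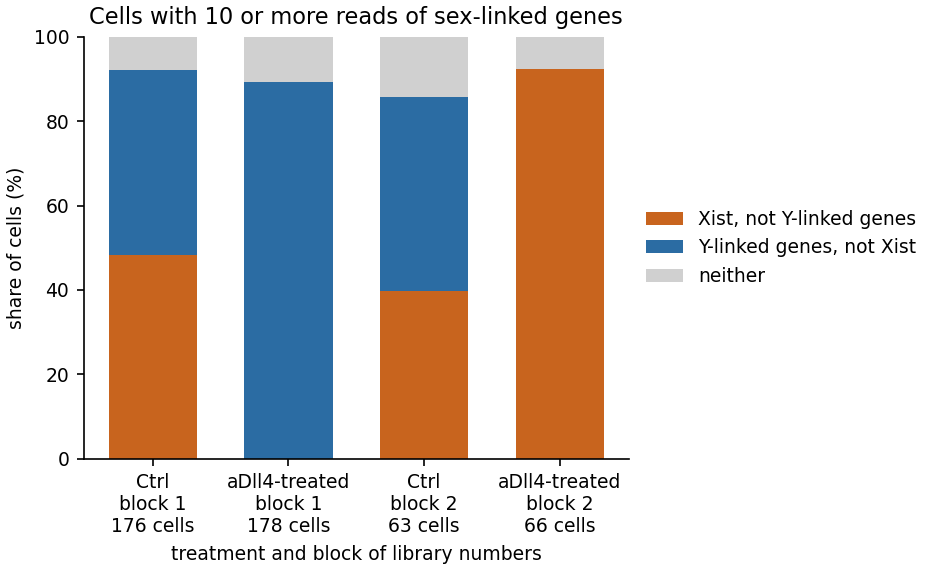
Share of cells (y axis, %) with 10 or more reads of Xist, of Y-linked genes, or of neither, by treatment and block of library numbers (x axis). Treated cells of block 1 held 0 Xist-positive cells and those of block 2 held 0 Y-positive cells, while Ctrl cells of both blocks held both.

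The second comparison asked whether cells were spread differently over the clusters. Cluster 1, with the most Dll4, held 40.6% of Ctrl cells (34.3 to 47.1%) and 35.2% of treated cells (29.3 to 41.6%), a difference of -5.34 points (-13.9 to 3.29). Cluster 2 held 30.5% and 29.5%, cluster 3 12.97% and 14.8%, cluster 4 4.18% and 4.92%, and cluster 5 2.51% and 2.87%. The hematopoietic clusters 6 and 7 together held 9.21% of Ctrl cells (5.86 to 13.6%) and 12.7% of treated cells (8.80 to 17.5%), a difference of 3.50 points (-2.14 to 9.16). Cluster 6 alone held 5.86% and 7.79%, and cluster 7 3.35% and 4.92%. No interval of a difference excluded 0, and these intervals leave out the spread between embryos. Genes that mark cluster 1, Dll4 among them, themselves differed between treatments. Cells reassigned without the Notch lists and the named genes gave cluster 1 shares of 44.8% and 36.1%, a difference of -8.70 points (-17.3 to 0.04). The reassignment kept 76.2% of Ctrl and 74.2% of treated cells in their cluster. Its centroids came from Ctrl cells, and other genes that differed between treatments were not left out. The reassignment therefore cannot tell a smaller cluster 1 from lower levels of its marker genes.

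**Figure D4:**
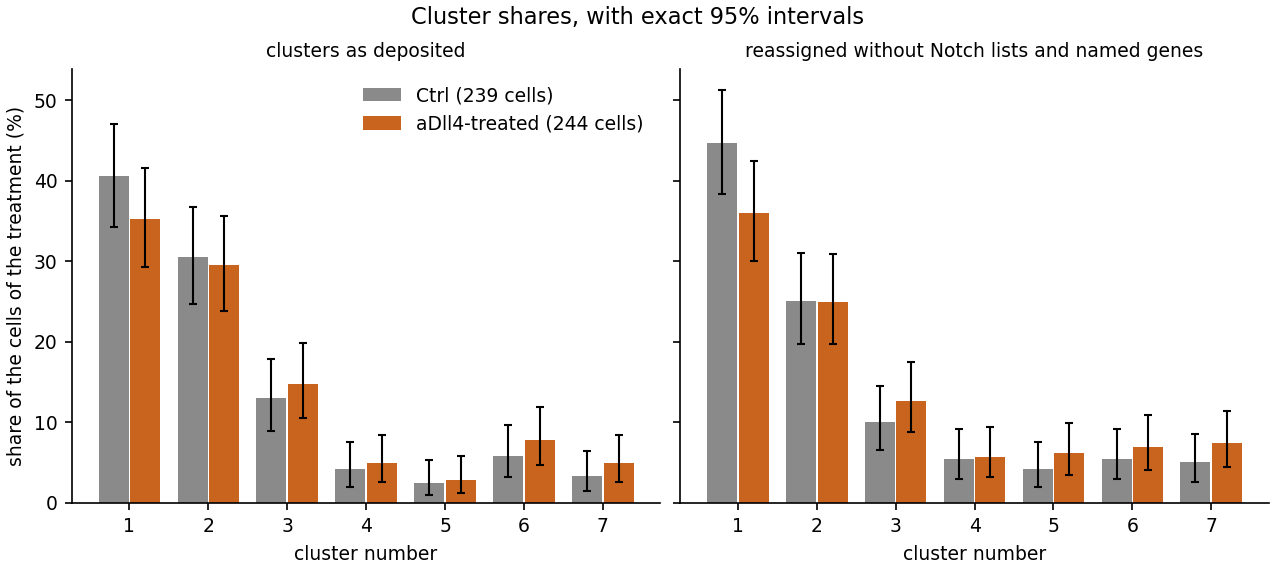
Share of the cells of each treatment (y axis, %) in clusters 1 to 7 (x axis), with exact 95% intervals as error bars, for the clusters as deposited (left) and as reassigned (right). Cluster 1 is lower in treated cells in both panels, 35.2% against 40.6% and 36.1% against 44.8%, with overlapping intervals.

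The third comparison asked whether the differences were also there among cells of a single cluster. In cluster 1 (97 Ctrl and 86 treated cells), the arterial median was -0.23 and the Notch target median -0.60, both outside their matched lists. Of 17 arterial genes there, 10 were lower and 7 higher. The pan-endothelial median was -0.040. Dll4 was at 600 CPM in Ctrl and 327 CPM in treated cells, with a log2 ratio of -1.17 in block 1 and 0.10 in block 2. Mycn (1.45), the apelin gene Apln (1.36), Gem (2.13) and the vasodilator peptide gene Adm (0.59) were the named genes higher in treated cells. Adm had 0.050 in block 1 and 1.88 in block 2. Tns1 (-1.66), Apoe (-1.15), Npr3 (-1.33) and Lyl1 (-1.23), a hematopoietic transcription factor gene, were lower. In block 2, with 16 and 13 cells of this cluster, the Notch target median was 0.60 and the arterial median -0.0069.

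In cluster 2 (73 and 72 cells), 14 of 17 arterial genes were lower, with a median of -0.76, which was -0.31 by mean log2(CPM + 1) and -0.41 in reassigned cells. The Notch target median was -0.30, within its matched lists, but -0.71 with cells thinned to equal depth. Mecom (-1.27), Sparcl1 (-0.48), Klhl4 (-0.61) and Tpst2 (-0.38) were lower, and Rgs16 (1.18), Cdc40 (1.16), B3gnt5 (0.59) and the mitotic kinase Plk1 (0.58) were higher. Plk1 had a ratio of -0.013 and Tpst2 of -0.070 in block 1, and Klhl4 of -0.15 in block 2. In cluster 3 (31 and 36 cells) the arterial median was -0.067 and the Notch target median -0.064, both within their matched lists. The arterial median was 1.26 in block 1 and -0.55 in block 2, and -0.45 in the cells reassigned to cluster 3. Fam129b (2.24), Lpcat1 (1.16), Eid1 (1.53) and Lrrc8c (0.63) were higher, and Fbxo3 (-0.78), Pam (-1.76), Map1b (-1.24) and Iqcb1 (-0.89) were lower there. Lrrc8c had 0.17 in block 1 and Iqcb1 -0.13 in block 2.

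Genes of G2 and M phase went opposite ways in the endothelial clusters. In cluster 1, 18 of 18 were lower in treated cells, with a median of -0.46. In cluster 2, 17 of 18 were higher, with a median of 0.44, and in cluster 3, 14 of 18, with a median of 0.37. The medians in block 1 were -0.30, 0.17 and 0.0065, and in block 2 -1.17, 1.14 and 0.67. With reassigned cells they were -0.45, 0.35 and 0.57, and with cells thinned to equal depth -0.24, 0.54 and 0.44. S phase genes did not follow this, with medians of 0.13 (-0.57 in block 2), 0.11 (-0.053 in block 1) and 0.55. In cluster 3, 8 of 9 mesenchymal and smooth muscle genes were also higher (median 1.93) and 13 of 16 pan-endothelial genes lower (-0.37). The mean log2(CPM + 1) of these lists was 0.58 and 6.92 in Ctrl and 0.93 and 6.39 in treated cells there. No test compared the clusters.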

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

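No paired analysis was possible because the labels name no pairs and no test was run. The cell numbers that the treatments share only count cells, and the 2 blocks, which hold cells of both treatments, are compared as values. Splits by sex, lists of MYC and NF-kappaB targets and comparisons without clusters were chosen after the data were seen, and the causes of the shifts below were not tested. Of the 24 named genes, 19 stayed on 1 side of 0 in all 23 settings. The naming rule itself required 1 sign in summed CPM, mean log2(CPM + 1) and both blocks. Much of this steadiness was therefore selected for. Over 25 settings, the Notch target median ran from -0.91 to -0.22, the arterial from -0.72 to -0.37, the pan-endothelial from -0.47 to -0.071, S phase from 0.052 to 0.43, and erythroid genes from 0.21 to 2.10. Depth was close between treatments, and thinning moved no Notch target, arterial or pan-endothelial median over all cells beyond the spread of matched lists. It did move the erythroid and megakaryocyte medians, to 0.55 and 0.86, the Notch target median in cluster 2 to -0.71, and the G2 and M phase median in cluster 1 to -0.24.

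A changed sign counts as reversed only for lists outside their matched lists, for named genes, and for share differences whose interval excludes 0, and otherwise as moved or within the spread. Of 696 list medians, 530 stayed within that spread and 32 reversed. Of 552 ratios of named genes, 25 moved beyond it and 9 reversed, and of 264 within clusters, 82 moved and 1 reversed. All reversed values, the moved ones of the Notch target, arterial, pan-endothelial, transition factor, pan-hematopoietic and S phase lists and of the cluster shares, and some others were these. With the mean of log2(CPM + 1), Notch targets had -0.22, arterial genes -0.50 (-0.31 in cluster 2), pan-endothelial -0.47, S phase 0.43 and stem cell genes 0.077. With cells weighted equally, arterial genes had -0.53 (-0.93 in cluster 2) and pan-hematopoietic 0.15. With a pseudocount of 10 CPM the arterial median was -0.37. In block 1 alone, transition factors had 0.85, stem cell genes 0.033, pan-hematopoietic 0.52, mesenchyme -0.77, mesonephric genes -0.64, Plk1 in cluster 2 -0.013, and arterial genes -0.47, -0.58 and 1.26 in clusters 1, 2 and 3. In block 2 alone, arterial genes had -0.39 (-0.00690, -0.57 and -0.55 in clusters 1, 2 and 3), transition factors -0.43, pan-hematopoietic -0.000376, p53 targets -0.014, interferon -0.049, MYC targets -0.032, NF-kappaB targets -0.19, Notch targets in cluster 1 0.60, immediate early genes 0.46, Rgs16 -0.15 and Birc3 -0.082. The cluster 2 share there differed by 8.15 points and that of cluster 5 by 4.55 points, with 0 of 63 Ctrl cells in cluster 5, which allows up to 4.76%.

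Leaving out a run moved the arterial median to -0.48 (run 4) and -0.49 (run 6), and the transition factors to 0.00706 (run 4), 0.49 (run 5) and 0.42 (run 6). It moved stem cell genes to 0.16 (run 5), pan-hematopoietic to 0.15 (run 2), and mesenchyme to -0.27, -0.20 and -0.19 (runs 4, 5 and 6). With equal cluster shares, arterial genes had -0.50, pan-endothelial -0.071, transition factors -0.15 and pan-hematopoietic -0.12. With no detection limit, Notch targets had -0.36. With a limit of 20% of cells, arterial genes had -0.37, transition factors -0.00379, pan-hematopoietic 0.15 and mesenchyme -0.29. Reassigned cells gave arterial medians of -0.41 in cluster 2 and -0.45 in cluster 3. Without the highest cell of each gene, neural genes had 0.12. Without clusters 4 and 5 the arterial median was -0.49. Without clusters 6 and 7, transition factors had -0.21, pan-hematopoietic -0.12, myeloid -0.035 and megakaryocyte -0.22.

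Among Xist-positive cells, Notch targets had -0.28, arterial genes -0.45, stem cell 0.22, pan-hematopoietic 0.52, S phase 0.28, NF-kappaB targets -0.52, Slc1a5 -0.079, Rgs16 -0.51 and Birc3 -0.25. Among Y-positive cells, pan-endothelial genes had -0.31, transition factors 0.32, glycolysis -0.013, mesenchyme -0.63 and neural genes 0.20. Among Y-positive cells of block 1, Notch targets had -0.91, arterial genes -0.48, pan-endothelial -0.28, transition factors 1.59, pan-hematopoietic 1.44, S phase 0.34, erythroid 2.10, megakaryocyte 3.91, mesenchyme -0.37 and neural genes 1.34. Among Xist-positive cells of block 2, arterial genes had -0.43, pan-endothelial -0.32, transition factors -0.43, stem cell 0.024, S phase 0.052, mesenchyme 2.77, NF-kappaB targets -0.62, Rgs16 -1.07, H2-K1 -0.54, Birc3 -0.92 and Trmt6 -0.54.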

Other observations

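The tests of the megakaryocyte and erythroid genes, the splits by sex, the share of cells without a sex call, the comparisons without clusters and the lists of MYC and NF-kappaB targets were chosen after the data were seen.

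Within the endothelial clusters, other gene groups stood apart too. Their values here are pooled over both blocks. Over all cells, the interferon response median was 0.57 in block 1 and -0.049 in block 2. The tip cell median was 0.038 and -0.31, and that of glycolysis and hypoxia 0.11 and 0.20. In cluster 1, all 6 interferon response genes were higher in treated cells, with a median log2 ratio of 0.72, and tip cell genes had a median of 0.37, among them Apln (65.6 CPM in Ctrl and 170 CPM in treated cells). In cluster 3, 7 of 10 tip cell genes were lower (-1.05), though their mean log2(CPM + 1) was 1.89 in Ctrl and 1.78 in treated cells, and 5 of 6 interferon response genes were higher (0.87). In cluster 2, 9 of 12 genes of glycolysis and hypoxia were higher (0.24), 9 of 10 pan-hematopoietic genes were lower (-0.31), and 6 of 7 erythroid genes were higher (2.06). The mean log2(CPM + 1) of the erythroid list there was only 0.22 in Ctrl and 0.39 in treated cells, near the floor.

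The lower arterial level of treated cells was weighed first. With equal cluster shares the arterial median was -0.50, so cluster shares did not account for it as a whole. With all cells thinned to 1 depth it was -0.56. CPM is already scaled by total reads, so thinning mainly reweights cells and decides little about depth. Within 1 sex and block the arterial median remained below the matched lists, which argues against the sex ratio. It was -0.48 among Y-positive cells of block 1 and -0.43 among Xist-positive cells of block 2. Over the Xist-positive cells of both blocks it was -0.45, but all treated cells there were of block 2. Differences between embryos stay open, because the labels name none and treated cells of each block were of 1 sex. Xist-positive and Y-positive Ctrl cells must come from different embryos, and their arterial medians differed by -0.015 in block 1 and by 0.30 in block 2. The value of block 2 lay outside the matched lists of that contrast (-0.28 to 0.28). The treatment gave -0.48 and -0.43 among cells of 1 sex, so embryo and treatment cannot be told apart here.

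The second pattern was the sex of the cells. Cells with 10 reads of both Xist and Y-linked genes made up 0% of all cells, as separate male and female embryos would give. Female cells that had lost Xist would have had reads of neither. Cells with neither made up 10.7% of the treated cells of block 1 (6.55 to 16.2%), while 48.3% of its Ctrl cells (40.7 to 55.9%) were Xist-positive, which argues against loss of Xist as the whole cause there. A possible explanation is that the treated cells of each block came from few embryos, or from 1. No biological explanation was tested.

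The third pattern was the higher megakaryocyte and erythroid genes of treated cells. With equal cluster shares, the members of both lists together had a median of 0.54, above their matched lists, which argues against the shares of clusters 6 and 7 as the whole cause. Without the 5 highest cells of each gene in each treatment it was 0.92, but cluster 7 held 8 Ctrl and 12 treated cells, so this left more high cells in the treated group, and a few cells with very high counts stay open. Megakaryocyte genes had a median of -0.22 without clusters 6 and 7, which held 22 Ctrl and 31 treated cells. Xist-positive over Y-positive Ctrl cells gave megakaryocyte medians of 2.85 in block 1 and -1.25 in block 2, so sampling of embryos may give differences of this size without treatment.

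One hypothesis was that higher Mycn and Slc1a5 go with a wider MYC program. Of 34 MYC targets of ribosome biogenesis, 32 were higher in treated cells, with a median of 0.16 that 3 of 10000 matched lists reached, in line with it. The median was 0.28 in block 1 and -0.032 in block 2, and 0.35 and 0.25 in the same-sex comparisons. Xist-positive over Y-positive Ctrl cells gave 0.060 in block 1 and -0.47 in block 2, so embryos may differ by as much. Another was that higher Birc3 goes with NF-kappaB targets. Of 17 measured targets other than Birc3 and Nfkbia, 13 were higher, with a median of 0.36, among them Nfkbib, Rela, Sod2 and Relb, but the median was -0.19 in block 2 and -0.62 among its Xist-positive cells. The NF-kappaB difference may thus belong to block 1, where treated cells with a call were Y-positive.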
